A study of Homo sapiens with 30 samples.

How the data were processed

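The submitters targeted exon 2 of FOXM1 with Cas9 ribonucleoprotein by electroporation, grew single clones by limiting dilution and checked them by Western blot and Sanger sequencing. A lentiviral vector carrying the FOXM1c isoform was put back into knockout cells, which were then sorted for GFP. Poly-A RNA was sequenced on a DNBSEQ instrument as paired ends of 100 bases, and the processing notes of the submitters name the human genome build hg19. The aligner and the counting tool are not given in the sources used here. For OPM2 the deposited values are FPKM, as the header of the deposited table states. For Delta47 the table names no unit, so its deposited values were treated as a signal, called here the authors' expression value. No counts were used, so the depth of each library is unknown. Relative steps of single reads were read from 2206 sparse genes in OPM2 and 1850 in Delta47. The pair of libraries with the fewest usable genes had 11 in OPM2 and 13 in Delta47. The steps lay between −0.09 and 0.11 (log2) and between −0.12 and 0.19 (log2). The SD of the estimates from pairs of libraries was 0.11 and 0.20.

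Of 30 libraries, 27 were used. The names of the KO2R columns lack the clone number and were matched by the letter R, which only these Delta47 samples carry. The 3 remaining Delta47 columns were not used, because their name did not match 1 sample, and the Delta47 empty-vector group was therefore not analysed here. The tables held 16407 genes for OPM2 and 17286 for Delta47, of which 23 and 24 symbols had been turned into dates and were renamed. Values were taken as log2(value + 1) with no further scaling. Genes at 1 or more in at least 3 libraries of a line were tested, 10309 in OPM2 and 11001 in Delta47. One model per line was fitted with limma-trend (limma 3.58.1, R 4.3.3) over all groups, with two-sided moderated tests and Benjamini-Hochberg adjustment within each comparison. A gene was called at an adjusted p below 0.05. Fold changes are on the log2 scale with the standard error (SE) of the fit, and group means are given with their standard deviation (SD, n = 3). The labels do not state whether the 3 replicates of a group are independent cultures, so the p-values measure a spread between libraries which may be technical.

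Gene lists were tested against the other genes with limma's camera at its preset correlation of 0.01, again with a correlation estimated per list, and with fry, which asks if a list moves one way on balance. Lists with fewer than 5 tested genes had no camera test. A list of myeloma translocation and cyclin D genes was also tested and is mentioned only where its direction turned with fry. The lists reported are FOXM1 and other late cell cycle genes, G1/S and E2F genes, replication-dependent histones, endoplasmic reticulum stress and XBP1 genes, ATF4 amino acid response, HSP90 and heat shock chaperones, MYC and ribosome biogenesis, plasma cell identity, MHC class II, interferon-stimulated genes, NF-kB target genes, cholesterol synthesis, oxidative phosphorylation, the tricarboxylic acid cycle, glycolysis, hypoxia, proteasome subunits, and markers of B cells, epithelial cells and stromal or endothelial cells.

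The comparisons, the lists, the rule for naming genes and most of the other settings tried were chosen before the data were examined. The comparison of Delta47 KO2R with untransduced KO2, the count of its reversed genes against KO1, the comparison of OPM2 KO1R with untransduced KO1, the removal of length trends and the fits without 2 OPM2 libraries were chosen after the data were seen. The rule names FOXM1 always. For each line it names the 8 strongest rises and the 8 strongest falls called in the same direction in both knockouts, ranked by the smaller of the 2 absolute log2 fold changes, with a group mean of at least 5 in at least 1 of WT, KO1 and KO2. It names 6 genes each way for the vector comparison, 6 each way for genes reversed by the vector, 8 each way for genes changed in both lines, up to 4 members of a described list by smallest adjusted p, and 30 fixed genes. Genes named outside this rule are marked as chosen after their values were seen.

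In a test of the fit, values were simulated for every gene around its mean, with its spread within groups and no difference between groups. In 200 genes the simulated KO1 values were then raised or lowered by a known factor on the log2(value + 1) scale. These simulated data held no library that stands apart and no correlation between genes. OPM2 recovered 76.1%, 92.5% and 100% of genes changed by 1.5, 2 and 4 times, and Delta47 recovered 100%, 98.5% and 100%. Of the genes left unchanged, 8 were called in OPM2 and 17 in Delta47.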

Results

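RNA was sequenced from a pair of human multiple myeloma cell lines, OPM2 and Delta47, in which the transcription factor gene FOXM1 had been knocked out and then put back. Each line has an unedited group (WT) and 2 knockout clones (KO1 and KO2). OPM2 KO1 also carries an empty vector (KO1EV) or a FOXM1c vector (KO1R), and Delta47 KO2 carries the FOXM1c vector (KO2R). The Delta47 vector columns carry the letter R but not the clone number, and were read as KO2R because no other Delta47 samples have an R in their name. Each group has 3 libraries. The values were FPKM in OPM2, with column totals of 510776 to 566016, and the authors' expression value in Delta47, with column totals of 534185 to 633778. These totals are not read counts, and the depth is unknown. The knockout clones were compared with WT to ask which genes change with loss of FOXM1. Each knockout group is a single clone, so a difference from WT can also belong to that clone. The p-values of such a comparison do not measure a spread between clones. The vector groups were compared with their knockout background to ask which changes turn back when FOXM1 is returned.

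FOXM1 transcript fell to about the same level in each Delta47 clone and further in KO2 than in KO1 of OPM2. In OPM2 the mean was 175.9 ± 0.804 FPKM (SD, n = 3) in WT, 92.06 ± 1.08 in KO1 and 62.13 ± 6.69 in KO2. The log2 fold change against WT was −0.93 ± 0.07 (SE) in KO1 (adjusted p = 1.09e-06) and −1.49 ± 0.07 in KO2 (adjusted p = 1.28e-08). KO1EV had 106.7 ± 1.85 FPKM. Its libraries (105.33 to 108.77) all lay above those of KO1 (91.24 to 93.28), but with the spread pooled over all groups the difference was not called (0.21 ± 0.07, adjusted p = 0.111). KO1R had 277.5 ± 14.4 FPKM, above KO1EV by 1.37 ± 0.07 (adjusted p = 6.36e-08). In Delta47 the authors' expression value was 88.92 ± 1.88 in WT, 47.95 ± 1.85 in KO1, 46.19 ± 0.883 in KO2 and 99.37 ± 4.37 in KO2R. The log2 fold changes were −0.88 ± 0.04 in KO1 (adjusted p = 4.19e-11), −0.93 ± 0.04 in KO2 (adjusted p = 1.3e-11) and 1.09 ± 0.04 in KO2R against KO2 (adjusted p = 1.02e-11). A transcript level does not measure the protein, and reads from edited transcripts count here too.

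**Figure D1:**
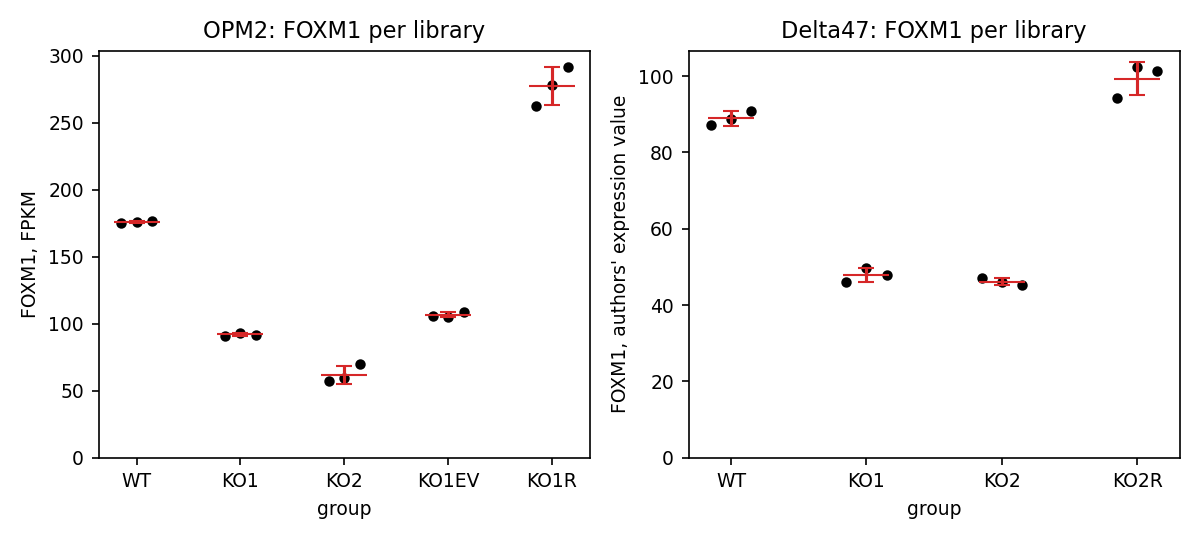
FOXM1 transcript per library (dots) with the group mean and SD (red), in FPKM for OPM2 (left) and as the authors' expression value for Delta47 (right). In OPM2 the mean falls from 175.9 in WT to 92.06 in KO1 and 62.13 in KO2, and it reaches 277.5 in KO1R.

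CDC25B and PLK1 fell in each knockout clone and rose in each FOXM1 vector group. CDC25B fell in OPM2 by log2 −1.40 ± 0.07 in KO1 (adjusted p = 2.11e-08) and −1.11 ± 0.07 in KO2 (adjusted p = 2.17e-07), and it was higher by 1.02 ± 0.07 in KO1R than in KO1EV (adjusted p = 7.43e-07). In Delta47 it changed by −0.83 ± 0.04, −0.90 ± 0.04 and 1.10 ± 0.04 in KO1, KO2 and KO2R. PLK1 changed by −1.17 ± 0.07, −1.09 ± 0.07 and 0.92 ± 0.07 in the OPM2 comparisons and by −0.98 ± 0.04, −0.96 ± 0.04 and 0.73 ± 0.04 in those of Delta47. OPM2 KO1EV was already above KO1 in CDC25B by 0.48 ± 0.07 (adjusted p = 0.000995) and in PLK1 by 0.41 ± 0.07 (adjusted p = 0.00204). CCNB1, NEK2, LDHA and SLC2A1 fell in all 4 knockout clones and rose in the vector group of each line. CCNB1 rose by 1.13 ± 0.11 in KO1R and by 0.98 ± 0.05 in KO2R. SLC2A1, a glucose transporter gene, fell by 1.46 ± 0.06 and 1.38 ± 0.06 in Delta47 KO1 and KO2 and rose by 1.53 ± 0.06 in KO2R. LDHA rose by 0.83 ± 0.06 in KO1R and by 1.32 ± 0.04 in KO2R. HK2 fell in all 4 knockout clones and rose in KO1R by 1.00 ± 0.10 (adjusted p = 4.11e-05), but its change in KO2R was not called (0.49 ± 0.24, adjusted p = 0.0845). ENO1, PKM and PGK1, glycolysis genes of the fixed set, did not follow in OPM2. They were called higher in KO1 than in WT, but ENO1 and PKM lost that call without any 1 of the 6 libraries (adjusted p = 0.0649 to 0.143). PGK1 lost it without KO1 replicate 3 (adjusted p = 0.0501). None of them was called in KO2 (0.36, −0.01 and 0.17) or in KO1R against KO1EV (−0.04, −0.13 and 0). Other cell cycle genes of the fixed set went other ways. AURKB was not called in the OPM2 clones (0.20 and −0.13) and was higher in Delta47 KO2R than in KO2 (0.28, but −0.029 with the length trend removed), and BIRC5 rose in both Delta47 clones (0.39 and 0.35). CENPF and MKI67 fell in both Delta47 clones and again in KO2R (−0.40 and −0.55, without removal of the length trend). Longer transcripts tended to be lower in KO2R than in KO2 (Spearman's rho −0.504). In OPM2 CENPF was higher in KO1R than in KO1EV (0.49, adjusted p = 0.0468), a call lost without any 1 of these 6 libraries (adjusted p = 0.0927 to 0.143).

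**Figure D2:**
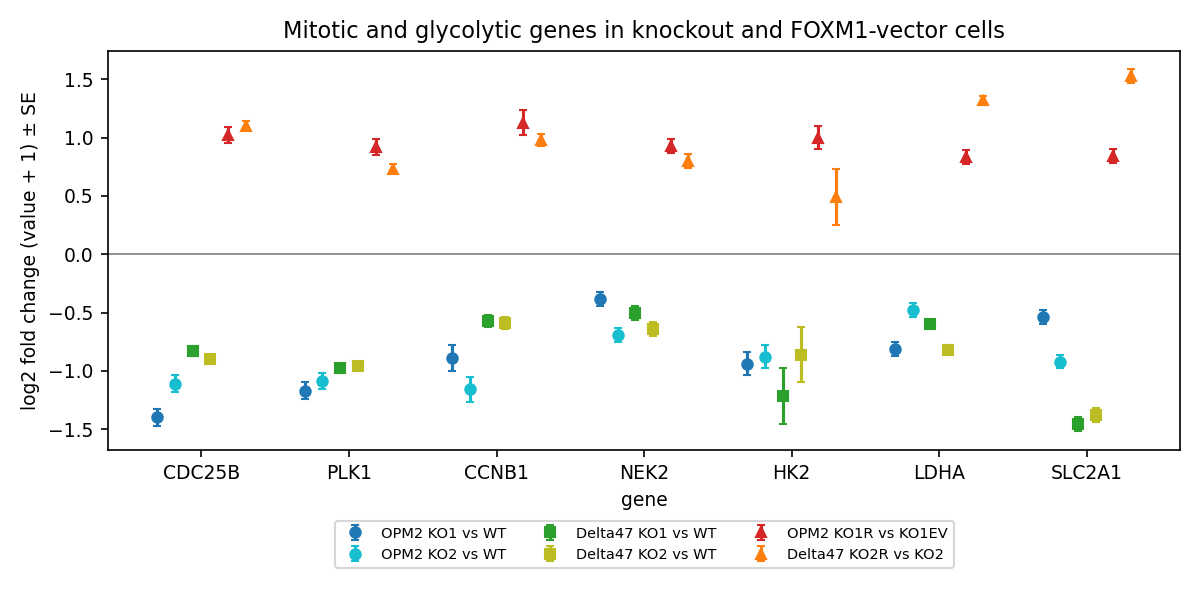
Log2 fold change of 7 genes in 6 comparisons, with the SE of the limma fit as bars. Fixed genes that went other ways, such as AURKB, BIRC5, ENO1 and PKM, are not shown. CDC25B and PLK1 lie below 0 in the knockout comparisons of each line and above 0 in each FOXM1 vector comparison.

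In OPM2, each knockout clone differed from WT in many genes, and the clones differed from each other. EEF1A2 rose from 49.86 ± 2.62 FPKM in WT to 552.7 ± 27.9 in KO1 (log2 3.44 ± 0.08, adjusted p = 8.91e-12) and 308.7 ± 36.5 in KO2 (2.60 ± 0.08, adjusted p = 2.34e-10). PDIA2, which encodes a protein disulfide isomerase, rose by 2.17 ± 0.08 in KO1 and 3.85 ± 0.08 in KO2. ARHGDIG, THEMIS, VAV1 and ZNF544 also rose in both clones. HLTF, a DNA repair helicase gene, fell from 6.343 FPKM to 0.4633 in KO1 and 0.4567 in KO2. GSTM1 fell by 1.88 ± 0.13 and 2.80 ± 0.13, and BMF, ACAA2 and ETFB fell in both clones. The plasma cell surface gene SDC1 fell by 0.29 ± 0.06 in KO1 (adjusted p = 0.00524) and by 0.31 ± 0.06 in KO2 (adjusted p = 0.00369), while MYC, NSD2, CCND2, MCL1, XBP1 and CDKN1A were not called in either clone.

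KO1 against WT called 2187 genes in OPM2, 1494 higher and 693 lower, of which 107 and 38 changed at least 2-fold. With quantile scaling the split was 1080 higher and 1143 lower. With only the groups compared in the fit, 3645 were higher and 1968 lower. KO2 against WT called 1480 genes, 674 higher and 806 lower, with 36 and 52 changed at least 2-fold. With only the groups compared in the fit, KO2 called 390 genes, 137 higher and 253 lower. Without KO2 replicate 3 and KO1EV replicate 3, which stand apart from their groups, the counts were 6068 (3915 higher, 2153 lower) for KO1 and 4243 (1987 higher, 2256 lower) for KO2. Leaving out single libraries moved these counts by more than 1.5 times. For KO1 the count was 1224 and 1310 without KO1 replicates 2 and 3 and 1358, 1260 and 1436 without WT replicates 1, 2 and 3, and for KO2 it was 3131 without KO2 replicate 3 and 937 without WT replicate 2. Between KO2 and KO1, 3086 genes differed. The 2 clones shared 193 genes called higher and 173 called lower, against 97.7 and 54.2 if independent, and 201 were called in opposite directions, against 162. With quantile scaling 158 were shared higher and 244 lower. Genes shared in either direction numbered 623 without KO2 replicate 3 and 243, 210 and 241 without WT replicates 1, 2 and 3, where all libraries gave 366, and 946 without the 2 libraries that stand apart. They numbered 162 with only the groups compared in each fit. Across genes, the log2 fold changes of the clones had a Pearson's r of 0.267. Both clones were compared with the same 3 WT libraries, which cannot be split into parts of at least 2, and simulated data with shared controls and no change gave an r of 0.499. The covariance was 0.0257, against 0.0104 in those simulations, so the shared controls could produce part of it. The simulated WT libraries, however, had a spread pooled over all groups, the 2 libraries that stand apart included. The real WT libraries deviated less from each other (SD over genes 0.1 to 0.139, against 0.533 for KO2 replicate 3). The part due to shared controls may therefore be overstated. Genes are not independent replicates.

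Among lists of genes in OPM2 KO1, few members were called in most of the lists that camera called, and those list calls rest on its preset correlation. None of them held with an estimated correlation (adjusted p = 0.974 with an estimated correlation for each). Of 30 tested stress and XBP1 genes, 0 were called higher and 2 lower, with the same counts adjusted over the list alone (median log2 −0.428, camera adjusted p = 8.07e-06). Plasma cell identity genes had 1 higher and 5 lower of 21, also when adjusted over the list alone (adjusted p = 0.000212). The ATF4 list had 1 lower of 25, and 0 adjusted over the list alone (adjusted p = 0.000975). HSP90 and heat shock chaperones had 5 higher and 1 lower of 24, and 7 and 1 adjusted over the list alone, and MYC and ribosome biogenesis genes had 1 higher of 40, and 0 adjusted over the list alone (both adjusted p = 0.0312). For late cell cycle genes 14 were higher and 11 lower of 46, and 15 and 11 adjusted over the list alone. Their median was 0.148, their mean 0.006 and the test pointed down (adjusted p = 0.678), so these differ in sign. Without the 2 libraries that stand apart, 28 stress and XBP1 genes were lower and 0 higher (adjusted p = 1.43e-18, and adjusted p = 0.000481 with an estimated correlation). The libraries left out were picked after their stress genes were seen, and neither belongs to this comparison, although both enter the spread of the fit.

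In OPM2 KO2, most members of the cell cycle and cholesterol synthesis lists were not called. With an estimated correlation no list was called, the MHC class II genes having an adjusted p = 0.497 with an estimated correlation and the other lists 0.940. Late cell cycle genes had 1 higher and 10 lower of 46, and 3 and 15 adjusted over the list alone, and G1/S and E2F genes had 8 lower of 42, and 11 adjusted over the list alone (both adjusted p = 0.000253). Cholesterol synthesis genes had 8 higher of 24, and 11 adjusted over the list alone (adjusted p = 0.000257). MHC class II genes had 4 higher of 7, also when adjusted over the list alone (adjusted p = 0.00059), led by HLA-DRA (1.27 ± 0.07, adjusted p = 1.14e-07) with HLA-DRB1 (1.01 ± 0.14). Proteasome subunits had 3 higher of 31, and 1 adjusted over the list alone (adjusted p = 0.00349). Stress and XBP1 genes had 0 called over all 3 KO2 libraries (limma, median 0.138, adjusted p = 0.296). The KO2 libraries differed in these genes, with list means (log2) of 7.315, 7.317 and 5.916 in replicates 1, 2 and 3. A test of the list without replicate 3 is not given, since that library was set apart after these genes were seen.

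KO2 replicate 3 and KO1EV replicate 3 of OPM2 differed from the other libraries of their groups in stress genes. These genes were chosen after their values were seen. In KO2, DDIT3 had 79.34 and 81.09 FPKM in replicates 1 and 2 and 7.04 in replicate 3, and in KO1EV it had 39.26, 38.2 and 9.45. INHBE had 99.99, 96.44 and 6.62 FPKM in KO2 and 60.19, 61.56 and 9.35 in KO1EV. The chaperone gene HSPA8 moved the other way, with 352.36, 349.71 and 1495.33 FPKM in KO2 and 766.91, 759.53 and 1416.37 in KO1EV. HSPA5 was lower in KO2 replicate 3 (105.9 against 246.9 and 254.43 FPKM) but not in KO1EV replicate 3 (122.25 against 118.61 and 118.8). The 3 KO1 libraries differed from WT in the same direction, with DDIT3 at 17.43 to 21.45 FPKM against 50.26 to 54.29 in WT and HSPA8 at 811.28 to 937 against 435.25 to 455.04, so the KO1 changes in the stress, ATF4 and HSP90 lists have the direction of this deviation. FOXM1 itself had 57.11, 59.55 and 69.73 FPKM in KO2. A library's log2 deviation was taken from the mean of the other 2 libraries of its group. The SD of this deviation over genes was 0.533 for KO2 replicate 3 and 0.271 for KO1EV replicate 3. The remaining OPM2 libraries had 0.1 to 0.282, the highest of them in KO2, where that mean contains replicate 3.

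**Figure D3:**
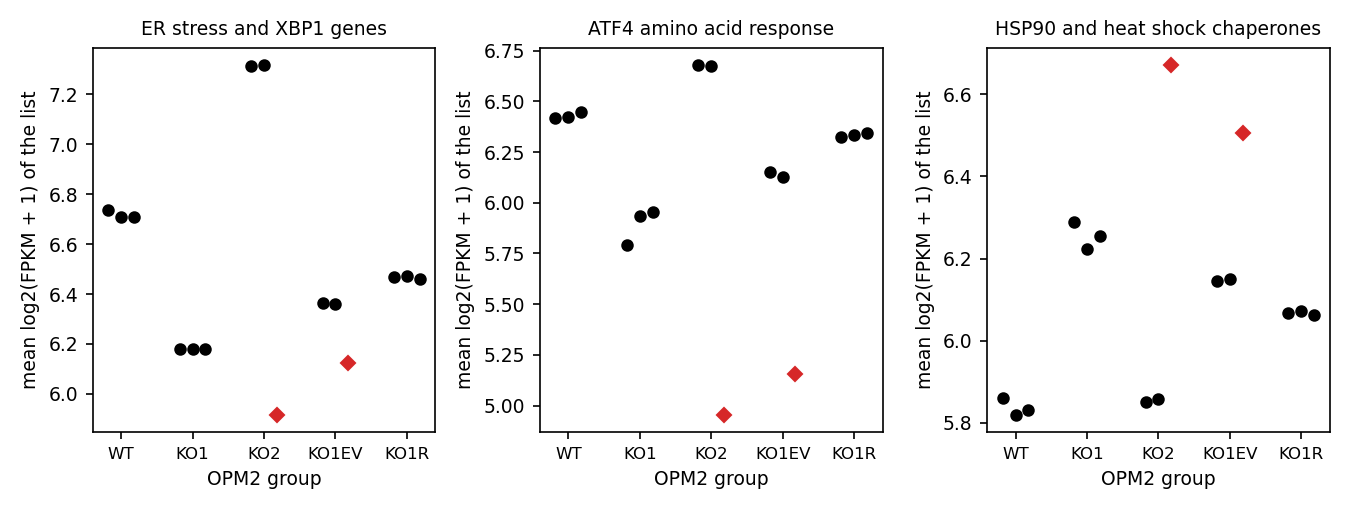
Mean log2(FPKM + 1) of 3 gene lists in each OPM2 library. Red diamonds mark KO2 replicate 3 and KO1EV replicate 3, which lie below the other libraries of their groups in the stress and ATF4 lists and above them in the HSP90 list.

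In OPM2, 10 of 15 tested replication-dependent histone genes were called higher in KO1R than in KO1EV. Poly-A RNA was sequenced, so the histone values in both lines refer to polyadenylated transcripts. HIST1H1C rose from 32.67 ± 2.24 FPKM in KO1EV to 134.3 ± 4.19 in KO1R (2.01 ± 0.09, adjusted p = 2.18e-08), and HIST1H2BK rose from 18.73 ± 3.51 to 84.73 ± 2.33 (2.14 ± 0.13, adjusted p = 3.45e-07). In WT, KO1 and KO2, HIST1H1C had 23.63, 28.42 and 26.87 FPKM, and HIST1H2BK had 13.13, 18.51 and 20.23. Neither gene was lower in a knockout clone than in WT, so their rise in KO1R went past WT and reversed no knockout fall. HIST2H2AA3 and HIST2H2AA4 rose by 2.13 ± 0.11, with identical values that do not separate these paralogs. The strongest falls by the rule were PCP4 (−2.70 ± 0.23), MAGED1 (−2.67 ± 0.09), TSPO (−2.05 ± 0.24), ANO1 (−2.05 ± 0.10), ARHGDIG (−2.01 ± 0.14) and HLTF (−1.99 ± 0.09). Relative to untransduced KO1, however, HLTF was not called in KO1R (0.20, adjusted p = 0.105), PCP4 was not called (−0.17, adjusted p = 0.635) and MAGED1 was higher (0.29, adjusted p = 0.0291), so these falls reflect higher values in KO1EV. ETFB, BMF, CD33 and NLRP11 fell in KO1 and rose in KO1R, NLRP11 from −1.68 to 2.10 ± 0.12. ETFB, however, already had 9 ± 1.93 FPKM in KO1EV, against 7.593 ± 1.19 in WT and 28.26 ± 2.7 in KO1R. Its WT level was thus reached without the FOXM1 vector. ANO1, THEMIS and TSPO rose in KO1 and fell in KO1R. In KO2, however, NLRP11 rose (2.41) and TSPO had −0.98, against the direction in KO1. Several of the strongest knockout changes did not turn back. Relative to KO1, KO1R showed no called change in PDIA2 (0.21, adjusted p = 0.0979), ZNF544 (0.06, adjusted p = 0.749), GSTM1 (−0.23, adjusted p = 0.208) or ACAA2 (0.31, adjusted p = 0.218). VAV1 rose further (0.64, adjusted p = 3.49e-05), and EEF1A2 fell by little of its rise (−0.35, adjusted p = 0.00827).

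The vector comparison called 848 genes, 320 higher and 528 lower in KO1R than in KO1EV, with 35 and 25 changed at least 2-fold. With quantile scaling 426 were higher and 345 lower, and without the 2 libraries that stand apart 954 were higher and 1772 lower. The count fell to 505, 547 and 536 without KO1EV replicates 1, 2 and 3, and to 424 and 452 without KO1R replicates 1 and 2, and it was 1412 with only the groups compared in the fit. Genes called in KO1 against WT and in the opposite direction here numbered 272, of which 190 rose in KO1 and fell with the vector and 82 did the reverse, and 147 were called in the same direction in each (Fisher's exact test, two-sided p = 4.09e-07, odds ratio 2.92). Genes are not independent, as this test takes them to be, so its p-value does not measure a spread between clones or cultures. With quantile scaling the reversed genes split 115 and 126, and without the 2 libraries 945 and 451. Without 1 library the reversed genes fell to 162 and 171 (KO1 replicates 2 and 3), 165 and 176 (KO1EV replicates 1 and 2), 149 and 160 (KO1R replicates 1 and 2) and 169 (WT replicate 2), and with only the groups compared in each fit they numbered 733. Of the 272, 253 were called the same way in KO1R against untransduced KO1, but that comparison reuses the KO1 and KO1R libraries the genes were picked on, so this is largely built in. Replication-dependent histones had 10 higher of 15, and 12 adjusted over the list alone (median 1.039, adjusted p = 1.71e-16), a call that held with an estimated correlation (adjusted p = 0.000345 with an estimated correlation). Late cell cycle genes had 12 higher and 1 lower of 46, and 14 and 2 adjusted over the list alone (adjusted p = 2.46e-08, and adjusted p = 0.623 with an estimated correlation). Interferon-stimulated genes had 2 higher of 14, also when adjusted over the list alone (adjusted p = 0.00176, and adjusted p = 0.623 with an estimated correlation). One of these, BST2 (0.29, adjusted p = 0.0434), lost its call without KO1EV replicate 1 or 3 or any KO1R library (adjusted p = 0.0612 to 0.174).

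The empty vector itself was compared with untransduced KO1, a comparison that contains what transduction and sorting change and any other difference between the cultures. These are not separated. MAGED1 had 8.76 FPKM in KO1EV but 0.25 in KO1 and 0.527 in KO1R, and HLTF had 5.703, 0.463 and 0.683. HLA-DRA rose by 0.77 ± 0.07 (adjusted p = 4.82e-05) and SDC1 by 0.49 ± 0.06 (adjusted p = 0.00035). The comparison called 510 genes, 183 higher and 327 lower, and without the 2 libraries that stand apart 3302, 1298 higher and 2004 lower. It was 246 and 307 without KO1 replicates 2 and 3, and 299 and 329 without KO1EV replicates 1 and 2. Across genes the log2 fold change had a length trend (Spearman's rho −0.322). Oxidative phosphorylation genes had 4 higher of 50, also when adjusted over the list alone (adjusted p = 6.21e-10), and 3 with that trend removed (adjusted p = 1.41e-05). MHC class II genes had 1 higher of 7, and 4 higher and 1 lower adjusted over the list alone (adjusted p = 0.00466). Cholesterol synthesis genes had 2 higher of 24, and 3 adjusted over the list alone (adjusted p = 0.0272), and the tricarboxylic acid cycle list had 0 called of 21 by limma (adjusted p = 0.0498). With an estimated correlation none of these lists was called (adjusted p = 0.962 with an estimated correlation, or 0.866 for MHC class II).

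In Delta47, GPX1 fell from 11.41 in WT to 0.09667 in KO1 and 0.11 in KO2 (−3.50 ± 0.07 and −3.48 ± 0.07). TSPAN7 (−3.28 and −3.64), EPHA3 (−3.33 and −1.67), ANXA1 (−2.06 and −2.43) and MT2A (−1.76 and −2.56) fell in both clones. The chemokine gene CCL3 fell from 44.34 to 11.77 and 9.807. SH3BGRL was listed at 0 in WT and had 20.68 in KO1 and 14.22 in KO2. ZNF100 rose from 0.1367 to 6.357 and 6.493, and DMKN from 1.703 to 11.44 and 12.38. KRT81 and KRT86, which are close paralogs, rose by 3.41 and 3.46 in KO1. SLAMF7 changed by −1.49 ± 0.04 in KO1 and −2.67 ± 0.04 in KO2, and IRF4 by −0.40 ± 0.03 and −0.41 ± 0.03. Plasma cell genes went both ways, as CD38 rose by 0.54 and 0.35. SDC1 rose by 1.10 ± 0.03 (adjusted p = 2.69e-13) and 0.77 ± 0.03 (adjusted p = 1.66e-11), where it had fallen in OPM2, and the difference between the lines was not tested.

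KO1 against WT called 5789 genes in Delta47, 3177 higher and 2612 lower, with 65 and 82 changed at least 2-fold. KO2 against WT called 4791, 3122 higher and 1669 lower, with 63 and 93 changed at least 2-fold, and the split was 2459 and 2096 with quantile scaling. The clones shared 1883 genes called higher and 1127 called lower, against 902 and 396 if independent, and 253 were opposite, against 1220. With quantile scaling 1519 were shared higher and 1417 lower. The covariance of their log2 fold changes across genes was 0.0728, against 0.00302 in simulations with shared controls and no change, and r was 0.704, against 0.499.

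More late cell cycle genes were called lower than higher in both Delta47 clones. In KO1, 10 were higher and 21 lower of 46 (11 and 23 adjusted over the list alone), with an adjusted p = 0.0321, and adjusted p = 0.343 with an estimated correlation. In KO2, 6 were higher and 20 lower, also when adjusted over the list alone (adjusted p = 0.000298, and adjusted p = 0.0825 with an estimated correlation). None of the other Delta47 list calls against WT held with an estimated correlation either, the lowest being the ATF4 list in KO1 (adjusted p = 0.0726 with an estimated correlation). In KO1, the ATF4 list had 3 higher and 16 lower of 27, also when adjusted over the list alone (adjusted p = 0.00186). Interferon-stimulated genes had 16 higher and 4 lower of 27, and 17 and 5 adjusted over the list alone (adjusted p = 0.012), led by OAS2 (0.80 ± 0.04), with USP18 lower (−1.05). Glycolysis genes had 16 higher and 4 lower of 24, also when adjusted over the list alone (adjusted p = 0.0334), although LDHA and SLC2A1 fell. Oxidative phosphorylation genes had 39 higher and 3 lower of 50, also when adjusted over the list alone (adjusted p = 0.000109), but with the transcript length trend removed 16 were higher and 7 lower (adjusted p = 0.233).

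In KO2 of Delta47, NF-kB target genes had 4 higher and 8 lower of 15, also when adjusted over the list alone (adjusted p = 0.00649), with RELB (−1.44 ± 0.07) and TNFAIP3 (−1.30 ± 0.07) among the falls. Replication-dependent histones had 1 higher and 9 lower of 18 (adjusted p = 0.00422), G1/S and E2F genes 4 and 15 of 42 and cholesterol synthesis genes 2 and 10 of 24 (both adjusted p = 0.00649), each with the same counts adjusted over the list alone. Plasma cell identity genes had 8 higher and 10 lower of 20, also when adjusted over the list alone (adjusted p = 0.0448). Of 5 tested stromal and endothelial markers 3 were higher, also when adjusted over the list alone (adjusted p = 0.0115), with PECAM1 rising from 1.19 to 14.47. B cell markers were not called as a list in KO1 (adjusted p = 0.491) or KO2 (adjusted p = 0.273), where 3 of 8 were higher and 3 lower, and 3 and 4 adjusted over the list alone, and epithelial markers were not called in KO1 (adjusted p = 0.22) or KO2 (adjusted p = 0.679). In OPM2 KO1 the B cell markers were not called (adjusted p = 0.237).

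The Delta47 FOXM1 vector group was compared with untransduced KO2, so this comparison also contains whatever the vector and the sorting change. DDIT4 rose from 3.273 to 27.07 (2.72 ± 0.06, adjusted p = 9.79e-14), and SLC2A4 (1.71 ± 0.06) and SLC2A1 (1.53 ± 0.06) rose. DYNC1H1 (−1.16 ± 0.07), KRT81 (−1.15 ± 0.07) and PLEC (−1.07 ± 0.05) fell. Longer transcripts tended to be lower in this comparison (Spearman's rho −0.504), and these falls are given without removal of that trend. CCL3, SLAMF7 and ITM2A fell in KO1 and rose here, by 1.08 ± 0.08, 1.11 ± 0.04 and 1.41. AEBP1, ROBO1 and KRT81 rose in KO1 and fell here.

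The comparison called 6816 genes, 2773 higher and 4043 lower in KO2R than in KO2, with 20 and 6 changed at least 2-fold. The split was 3341 higher and 3418 lower with quantile scaling, 2085 and 4442 with the length trend removed, and 1715 and 4428 with length and GC trends removed. Across 10901 genes the log2 fold change correlated with transcript length, with a Spearman's rho of −0.504. To avoid the shared KO2 libraries, reversal was counted against KO1. Of genes called in KO1 against WT, 938 were called in the opposite direction in KO2R against KO2, and 3071 in the same direction (Fisher's exact test, two-sided p = 6.11e-274, odds ratio 0.0822). The test treats genes as independent, which they are not, so its p-value does not measure a spread between clones or cultures. With the length trend removed 1180 were opposite and 2284 the same. Among the 938, 633 rose in KO1 and fell with the vector and 305 did the reverse, or 461 and 426 with quantile scaling. Oxidative phosphorylation genes had 44 higher and 2 lower of 50, and 45 and 3 adjusted over the list alone (adjusted p = 3.16e-17). With the length trend removed 26 were higher and 11 lower (adjusted p = 9.99e-06). Hypoxia genes had 11 higher and 1 lower of 18, also when adjusted over the list alone (adjusted p = 0.000325). Replication-dependent histones had 11 higher of 18, also when adjusted over the list alone (adjusted p = 0.00236), and 1 higher and 3 lower with the length trend removed (adjusted p = 0.967). Proteasome subunits had 18 higher and 8 lower of 31, and 19 and 8 adjusted over the list alone (adjusted p = 0.0116), and 7 higher and 14 lower with the length trend removed (adjusted p = 0.825). With an estimated correlation none of these calls held, the histones and hypoxia genes having an adjusted p = 0.0573 with an estimated correlation.

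Genes changed in the same direction in all 4 knockout clones were few. Of 9530 genes tested in each line, 37 were called higher and 55 lower in all 4 clones and 29 were called in opposite directions between lines, against 26.8, 13.6 and 38.8 if the lines were independent (Fisher's exact test, two-sided p = 3.07e-08, odds ratio 9.56). This p-value also treats genes as independent, which they are not. With quantile scaling 25 were higher and 69 lower, and without the 2 OPM2 libraries that stand apart 90 and 92. Without OPM2 WT replicate 2 the count in either direction was 61, where all libraries gave 92. It was 53 with only the groups compared in each fit. The falls named by the rule were FOXM1, CDC25B, PLK1, HK2, GPSM2, IFI16, GLIPR1 and TSPAN7. GLIPR1 lost its OPM2 KO2 call without WT replicate 1, 2 or 3 (adjusted p = 0.0522 to 0.0603), and it was lower in KO1R than in KO1 (−1.38, adjusted p = 0.00221). TSPAN7 lost its OPM2 KO1 call without any 1 of the 6 KO1 and WT libraries (adjusted p = 0.0852 to 0.101). GPSM2 fell by 0.73 ± 0.08 and 1.43 ± 0.08 in the OPM2 clones and by 0.86 ± 0.06 in each Delta47 clone. The rises include IGFBP7 (1.32 and 0.65 in OPM2, 0.67 and 0.61 in Delta47), SLC16A3, SLC7A7 and the zinc finger genes ZNF100, ZNF257 and ZNF43.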

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

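The tests of mislabelling and of length and GC trends, here and in the comparison of the clones, were chosen after the results were seen. For the genes and lists in this part, the effects of KO1 and KO2 against WT had opposite signs in one line, and the difference between the clones was called in limma. In OPM2, NLRP11 had log2 −1.68 in KO1 and 2.41 in KO2, a difference of 4.09 (adjusted p = 7.87e-11). TSPO had 2.06 and −0.98, a difference of −3.04 (adjusted p = 9.19e-07). For E2F8 the values were 0.31 and −0.27, a difference of −0.58 (adjusted p = 0.00015), and for FGFR3 they were −0.35 and 0.32, a difference of 0.67 (adjusted p = 0.000114). The E2F8 call in KO2 was lost without KO2 replicate 1 or 2 or any WT library (adjusted p = 0.0985 to 0.139). FGFR3 lost its call in KO1 without KO1 replicate 1 or WT replicate 2 or 3 (0.0522 to 0.0694) and in KO2 without KO2 replicate 1 or 2 or WT replicate 1 or 2 (0.0868 to 0.13). In Delta47, HIST1H1C had 0.23 and −0.51, a difference of −0.74 (adjusted p = 9.22e-09). HIST1H2AC had 0.41 and −0.20, a difference of −0.61 (adjusted p = 8.47e-07), and its KO2 call was lost without WT replicate 2 (adjusted p = 0.0587). PRDM1 had −0.18 and 0.18, a difference of 0.36 (adjusted p = 2.74e-06). The Delta47 clone difference had a length trend (Spearman's rho 0.432 across genes). With that trend removed the differences were −0.51 for HIST1H1C (adjusted p = 4.18e-08), −0.50 for HIST1H2AC (adjusted p = 2.25e-06) and 0.30 for PRDM1 (adjusted p = 4.51e-06). Among lists in Delta47, interferon-stimulated genes had 4 higher and 14 lower in KO2 than in KO1 (adjusted p = 1.22e-05, and adjusted p = 0.00974 with an estimated correlation), and 5 higher and 14 lower with the length trend removed (adjusted p = 7.44e-06, and 0.0262 with an estimated correlation). Replication-dependent histones in Delta47 had 10 lower (adjusted p = 5.53e-05, and adjusted p = 0.0118 with an estimated correlation). With the length trend removed 1 was higher and 6 lower of 18 (adjusted p = 0.00722, and 0.0422 with an estimated correlation).

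In OPM2, endoplasmic reticulum stress and XBP1 genes were higher in KO2 than in KO1 (9 higher of 30, adjusted p = 1.21e-06, but adjusted p = 0.808 with an estimated correlation), while KO2 replicate 3 and KO1EV replicate 3 had low stress and ATF4 genes and high HSP90 genes. Over 16 genes that separate the groups, KO2 replicate 3 lay at a mean log2 distance of 0.535 from its own group and 1.43 from the next (WT), and KO1EV replicate 3 at 0.331 and 1.12 (KO1). Over these 16 genes, the distances argue against a wrong group label. An earlier test, by the side of the midpoint, was less clear, with 15 of 16 genes on the own side for KO2 replicate 3 (11 for WT) and 12 of 16 for KO1EV replicate 3 (10 for KO1). Over all tested genes, the mean Spearman's rho to the own group was 0.9545 for KO2 replicate 3 and 0.9872 for KO1EV replicate 3. Their highest rho to a single library of another group was 0.9876 and 0.9885, so the measure over all genes does not argue against a wrong label. The deviations of the 2 libraries correlated across genes (r = 0.751), and with length and GC trends removed r was 0.762, which argues against those trends as the source. A difference in the state of the cultures or their handling may account for the shared deviation and stays open, since no batch is labelled, and no biological explanation was tested.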

How the results depend on the processing

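The removal of length or GC trends and the fits without 2 OPM2 libraries were chosen after seeing the data. Of 341 calls for named genes, 332 kept direction and call with quantile scaling, 339 with a pseudocount of 0.1, 327 with no filter, 330 with the length trend removed, 330 with length and GC trends removed, and 152 against a fold of 1.5. Of 39 list calls, not counting those between KO2 and KO1, 1 was kept with an estimated correlation (the histones in OPM2 KO1R). With fry 22 were kept, and 31 with the length trend removed. The replicate numbers gave no regular pairing. The correlation of same-number pairs had a median of 0.0721 in OPM2 (9 of 30 above 0.1, highest 0.751 for KO1EV and KO2 replicate 3) and 0.0214 in Delta47 (4 of 18, highest 0.201), and 0 and 1 libraries were closest to their own number in every group. With a replicate block 337 of the gene calls were kept, and the counts were 2627, 1591, 975 and 553 in the order OPM2 KO1, KO2, KO1R and KO1EV, and 5709, 4695 and 6761 for Delta47 KO1, KO2 and KO2R. In those orders, adjusted p under 0.01 gave 952, 774, 359 and 252 in OPM2, with 162 genes in both OPM2 clones, 97 reversed, 572 reversed in Delta47 and 48 in both lines. A fold of 1.5 gave 103, 63, 42 and 19 in OPM2 and 226, 270 and 69 in Delta47. Stricter criteria call fewer genes by construction. With only the groups compared in each fit, OPM2 KO1, KO2 and KO1R gave 5613, 390 and 1412, both clones 162, reversed 733 and both lines 53. Without KO2 replicate 3 and KO1EV replicate 3 the OPM2 counts were 6068, 4243, 2726 and 3302, both clones 946, reversed 1396 and both lines 182. Leaving out 1 library gave 1224 to 1509, 937 to 3131, 424 to 576 and 246 to 597 in OPM2, 210 to 623 in both clones, 149 to 207 reversed and 61 to 136 in both lines. In Delta47 it gave 5043 to 5471, 4098 to 4326, 6199 to 6590, 2620 to 2817 in both clones and 808 to 916 reversed. Some Delta47 values in KO2R turned negative (log2). With quantile scaling these were PSMB4 −0.019, PKM −0.182, ENO1 −0.469 and SDC1 −0.159, and PGK1 in KO1 turned to −0.024. With the length trend removed they were PSMB1 −0.078, PSMB4 −0.13, HIST1H2BK −0.336, HIST1H1C −0.052, AURKB −0.029 and ENO1 −0.066. With length and GC trends removed they were PSMB1 −0.083, PSMB4 −0.086, HIST1H2BK −0.199 and TNFRSF17 −0.079. The direction of 6 list results turned. Without the 2 OPM2 libraries these were the ATF4 list (adjusted p = 1.78e-05), the MYC list (0.606) and plasma cell identity (0.0466) in KO2, and the ATF4 list in KO1EV (4.03e-07), which is partly built in, as those libraries were set apart after stress and ATF4 genes were seen. The myeloma translocation genes turned with fry in OPM2 KO2 (0.0499), and the proteasome list in KO2R with the length trend removed (0.825). The cause of these moves was not tested beyond what is stated. A count-based model with its own scaling and filter was not run for want of counts, and Delta47 KO2R and KO2 were not compared with an empty vector. The unknown depth limits what can be said of sparse genes.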

Other observations

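The tests of the length trend and of mixed cells were chosen after the results were seen, as was the comparison of Delta47 KO2R with KO2, while the counts over other splits of the remaining comparisons were planned. Each comparison of 3 libraries with 3 has 10 splits, and in each of the 7 comparisons 1 split, the real one, called as many genes. These splits are too few for a share under 0.05. Every other split also mixes libraries of the groups compared, so a difference between the groups enters the spread and lowers the count by construction. No conclusion is drawn from them. In OPM2 the real counts were 2187 (KO1 against WT), 1480 (KO2 against WT), 848 (KO1R against KO1EV) and 510 (KO1EV against KO1), and the highest other split called 0. In Delta47 they were 5789 (KO1), 4791 (KO2) and 6816 (KO2R against KO2), and the highest other split called 0, 0 and 1.

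In Delta47, KO2R differed from KO2 in many genes in the same direction as KO1 from WT, with no library shared between these comparisons, and the log2 fold changes had an r of 0.275 across genes. Each comparison had a length trend (Spearman's rho −0.392 in KO1 and −0.504 in KO2R). With the trend removed, r was 0.153, so the trend may account for part of the pattern. Lengths came from a single reference transcript per gene, so a length effect can remain after removal, and the rest of the pattern is not settled. With the trend removed hypoxia genes stayed called (adjusted p = 2.91e-06, and 0.0194 with an estimated correlation, where it was 0.0573 before). This argues against length as the whole source for the hypoxia list. Oxidative phosphorylation genes stayed called only at the preset correlation (adjusted p = 9.99e-06, and 0.48 with an estimated correlation) while their median fell from 0.367 to 0.10, which leaves length open, and the histones lost their call (adjusted p = 0.967), in line with a length trend. Effects of the vector or of sorting on these genes stay open, because no Delta47 empty-vector group was analysed here.

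OPM2 KO1EV expressed genes that were near 0 in KO1 and KO1R, chosen after their values were seen. Their level was 45.7 ± 6.67% (SE) of WT for GNG10, 47.1 ± 3.3% for MAGED1, 55.7 ± 6.01% for NMRAL1 and 89.9 ± 4.86% for HLTF. A mixture with unedited cells would give 1 share for all of them, and the gap from lowest to highest was 44.2 percentage points. FOXM1 in KO1EV stood 17.4 ± 1.48% of the way from KO1 to WT, below each of these shares. These values argue against unedited cells as the only source, and differences between cultures of the clone may be another, which was not tested.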
